A study of Gallus gallus with 40 samples.

How the data were processed

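Libraries of poly-A selected mRNA from 8 tissues of 5 roosters were sequenced as stranded, paired 150 nt reads, per the labels' protocols. Per the submitters' processing notes, reads were checked with FastQC, aligned with STAR 2.604a, counted per gene with featureCounts 1.6.3 and analysed with DESeq2. The deposited table holds raw fragment counts for 24107 genes and 40 libraries. Per the file headers, counting used exons grouped by gene of the GRCg6a annotation, paired reads, and no strand option, so reads of overlapping genes on opposite strands were not separated. Exons of 5802 genes share bases with another gene, and 2783 genes share over 10% of them. The DESeq2 output of the submitters was not used here.

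Gene positions were taken from the deposited table and symbols from its gene identifiers. Of 8631 genes with only a LOC identifier, 84 were given a symbol through the NCBI gene number in a newer annotation table. This left 15560 named genes and 8547 without a symbol. The genome sequence was not used here.

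Libraries were grouped by tissue and by the replicate number in their titles. The labels put the 8 libraries of a number in 1 animal, but in 3 libraries (testis replicate 1, kidney replicate 2 and testis replicate 2) the individual field holds another number. After tissue means were removed, libraries of the same number correlated with a mean r of 0.133 (−0.0385 to 0.421, over 0.1 in 91 of 140 pairs) across genes, and libraries of different numbers with a mean of −0.0334. For 39 of 40 libraries the mean correlation was highest with libraries of their own number. The fit with the animal as a block is given beside the fit without it for the counts of elevated genes and for named genes whose call differs. Block results of single list tests are not given. No 2 libraries were copies of each other (chi-square per degree of freedom 9.82 or more).

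Counts were filtered with filterByExpr by tissue, which left 19864 genes, and normalised with TMM in edgeR 4.0.16 under R 4.3.3. Levels are TMM-normalised CPM, and log2 CPM used a prior count of 2. A quasi-likelihood model with the 8 tissues as groups was fitted to all 40 libraries. Each tissue was tested against the equal-weight mean of the other 7, with Benjamini-Hochberg adjustment per contrast, and called at an adjusted p below 0.05 and a fold change of 2 or more. This mean was taken on the log scale, so log2 differences from it are not log2 ratios of mean CPM. Elevated genes were at least 4-fold higher with an adjusted p below 0.05 in each of 7 single comparisons. Heart and muscle, liver and kidney, and testis and brain were compared as pairs in the same fit. Differences between animals were tested as the 4 animal coefficients of a model with tissue and animal. Sets of genes were tested with camera at a preset inter-gene correlation of 0.01, with an estimated correlation and with fry (limma 3.58.1), for 23 lists with 9 to 35 measured members, 184 tests in all. The share of Z-linked genes was tested with Fisher's exact test.

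Tissue contrasts, pairs, lists, thresholds and the rule for named genes were chosen before the data were examined. Per tissue the rule took the 10 most abundant elevated genes with a symbol, and the 3 genes most abundant elsewhere among those called lower by 8-fold or more. It also took the 4 most abundant members of each list of the tissue and up to 3 members called lower. Per pair it took the 8 most abundant genes in each direction called at 4-fold or more, for animals the 6 genes with the smallest p, and for each list of no single tissue the 3 most abundant members where its p was smallest. Haemoglobin genes were named in any tissue. Some genes that the rule takes are not reported here.

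After TMM normalization 1 count equals 0.0923 CPM in muscle replicate 2, the highest, and 0.0184 in testis replicate 5, the lowest. A count of 0 allows up to 3 counts, or 0.0551 to 0.277 CPM by library. Detection and the shares of the most abundant genes used the full library total without TMM. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

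The procedure was tested on simulated data with 19864 genes. Every tissue had the same simulated baseline, and genes were changed only where their average log2 CPM was above 1. The results therefore do not show how calls behave for low genes or between tissues of different composition. Of 50 genes per size changed in brain by log2 −3, −2, 2 and 3, it called 49, 47, 49 and 50, and it called 8 unchanged genes. It called 47 of 50 genes raised by log2 3 elevated and 0 unchanged ones. In the test of animals, 156 of 200 genes changed by log2 1 in 1 animal were called, with 6 unchanged ones, and of the list tests the changed list was found and 0 random list tests passed. The simulated genes were drawn independently of each other, so these list results do not show how the list tests behave with correlated genes. In random regroupings of the real libraries 90 to 134 list tests passed.

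Alternatives were RLE and upper quartile normalization, no filter, DESeq2 1.42.0, glmTreat, the animal as a block by title and by individual field, the 3 libraries with 2 animal numbers left out, each pair fitted alone, elevated thresholds of 2-fold and 10-fold, and leaving out each replicate number and each library of a tissue. Detection was also counted at 0.5 and 5 CPM and after thinning to the smallest library, shares for the top 1 and 100 genes, and the test of animals without each tissue. Chosen after seeing the data were a fit without 7 doubted libraries (brain 2, intestine 1, kidney 3, liver 3, lung 1, muscle 3 and muscle 4), the test of animals without chromosome 16, the Z-linked share over genes with a symbol or with neighbours within 100 kb counted once, top shares without each animal, and the test of animals without animal 5 and on counts thinned to equal library totals. The 23 lists cover neuronal, glial, cardiomyocyte, fast muscle, enterocyte, kidney, hepatocyte, lung, germ line, sperm, Sertoli and Leydig genes, and genes of blood, stroma, cilia and metabolism.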

Results

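The series holds 40 RNA-seq libraries of poly-A selected mRNA from brain, heart, intestine, kidney, liver, lung, muscle and testis. The tissues came from 5 adult Leghorn roosters aged 12 months, with 5 libraries per tissue (n = 5 for every tissue value). Each library gave fragment counts for 24107 genes of the GRCg6a annotation. Total counts ranged from 12903529 in heart replicate 1 to 37082659 in intestine replicate 5. By tissue, the total counts per library were brain 20918816 to 31745675, heart 12903529 to 24782001, intestine 15806787 to 37082659, kidney 22233726 to 31267869, liver 18558149 to 33581989, lung 16180560 to 33838003, muscle 22477020 to 31875595 and testis 22302831 to 36703827. Gene levels are given as normalised CPM (counts scaled to the TMM-normalised library size), mean ± SD of the 5 libraries, and log2 differences with ± SE. This SE is the size of the log2 difference divided by the square root of the F statistic of its test. It is an approximation and not a separately estimated standard error. A gene was called elevated in a tissue when it was at least 4-fold higher, with an adjusted p below 0.05, than in each of the 7 other tissues. Folds given without a replicate or library keep the comparison tissue of the full data, which may then no longer be the next tissue.

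Testis had the most detected genes and muscle the fewest. At 1 CPM or more in all 5 libraries, 15789 genes were detected in testis, 13337 in kidney, 13241 in lung, 13132 in brain, 13070 in intestine, 11801 in heart, 11649 in liver and 9905 in muscle. All 8 tissues shared 8787 of these genes, and 2921 genes were detected in a single tissue, 1894 of them in testis. Muscle and liver mRNA was dominated by a few transcripts: the 10 most abundant genes took 29.6% ± 1.03 (SD, n = 5) of counts in muscle and 26.2% ± 1.51 in liver. That share was 14.7% ± 1.89 in heart, 10.6% ± 1.58 in lung, 9.98% ± 0.560 in kidney, 7.95% ± 1.11 in intestine, 5.00% ± 0.155 in brain and 3.21% ± 0.0833 in testis. On the multidimensional scaling plot most libraries lay with their tissue, but intestine and kidney lay close together and muscle replicate 3 lay beside the heart libraries. Of the 28 tissue pairs, kidney and liver differed in the fewest genes (6902) and muscle and testis in the most (14006), with a median of 10529.

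**Figure D1:**
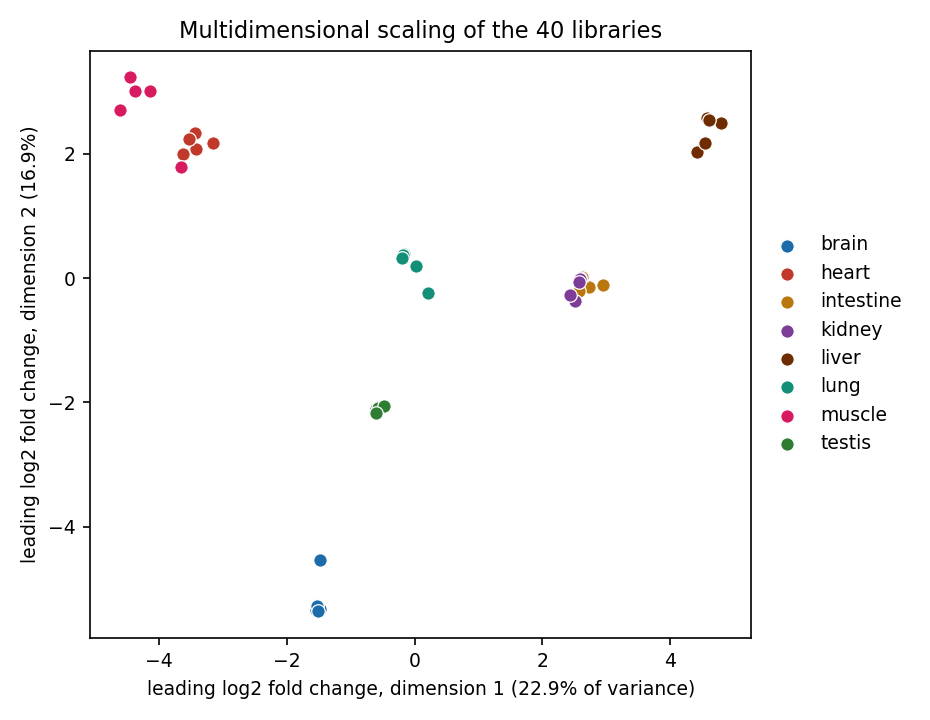
Multidimensional scaling of the 40 libraries on log2 fold changes, dimension 1 (22.9% of variance) against dimension 2 (16.9%); each point is a library, coloured by tissue. Most libraries lie with their tissue, but muscle replicate 3 lies beside the heart libraries, brain replicate 2 apart from the other 4 brain libraries, and intestine and kidney close together.

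Each tissue was then compared with the mean of the other 7, taken on the log scale, to ask which genes mark it. Testis had the most genes higher than that mean, 7429, and 2222 genes elevated over every other tissue. Brain followed with 5297 genes higher and 1025 elevated, ahead of muscle with 3905 and 401, liver with 3800 and 385, intestine with 4144 and 370, kidney with 3784 and 310, lung with 4223 and 221 and heart with 3200 and 196. Muscle had the most genes lower than the mean of the others, 7056, against 5148 in testis, 4131 in liver, 4061 in heart, 4019 in brain, 3601 in intestine, 3382 in lung and 2351 in kidney. Over all tested genes the median log2 difference was −0.686 in muscle. In the other tissues it lay between −0.242 in heart and 0.198 in testis. The muscle count thus comes from a distribution that was shifted down as a whole, so it is not a number of genes singly low in muscle. The elevated genes took 49.4% of counts in muscle and 44.8% in liver, but 20.6% in testis, 20.1% in heart, 19.8% in brain, 11.9% in intestine, 10.6% in kidney and 9.76% in lung. With the animal as a block, elevated genes numbered 998 in brain, 198 in heart, 359 in intestine, 317 in kidney, 388 in liver, 205 in lung, 403 in muscle and 2287 in testis. With glmTreat, elevated genes were tested for more than a 4-fold change and genes lower for more than a 2-fold change. Elevated genes then numbered 85 in lung, 232 in intestine and 200 in kidney, and genes lower 2243 in lung and 1297 in kidney. Calls used edgeR's quasi-likelihood test at an adjusted p below 0.05 and a fold change of 2 or more. The count ignored strand, so ALB, LDHA, YBX1, SLC1A3, PIGR, CLDN11, JCHAIN, TUBB4B, TEKT2 and CCDC40, each with over 10% of exon bases shared with another gene, are uncertain. CST3 and ODF2 share over 10% of exon bases with genes on the same strand and are uncertain for that reason. Reads of close paralogs, such as the myosin heavy chain MYH1E or the surfactant proteins SFTPA1 and SFTPA2, are uncertain as well.

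**Figure D2:**
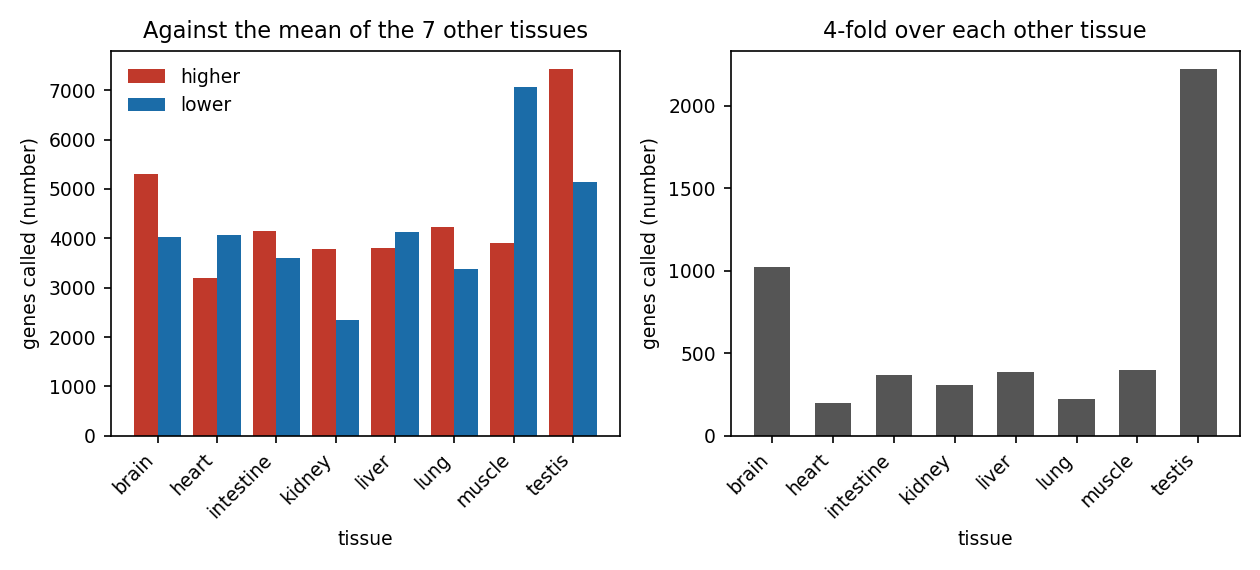
Number of genes per tissue that were higher than, lower than, or elevated over the other tissues, as bars by tissue. Testis has the most higher genes (7429) and elevated genes (2222), and muscle the most lower genes (7056).

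Brain was marked by neuronal and glial genes. The most abundant elevated gene was CAMK2A, the alpha subunit of a calcium-dependent kinase of excitatory synapses (chromosome 13, 13896807 to 13920952). It reached 2835 ± 1497 CPM (SD, n = 5) in brain, 15.7-fold over heart with 180.5 ± 84.7 (log2 3.97 ± 0.42, adjusted p = 2.1e-10). SLC1A2, an astrocyte glutamate transporter, stood at 2576 ± 829 CPM, 52.1-fold over heart. SLC17A6, which loads glutamate into synaptic vesicles (chromosome 5, 3033148 to 3064880), had 1015 ± 172 CPM against a highest other level of 0.586 ± 1.22 in muscle, a 1713-fold difference. The SD in muscle was above the mean there, so this fold rests on unevenly spread muscle libraries. CLSTN1, a synaptic calsyntenin, was 13.7-fold over heart at 2325 ± 236 CPM, and GPM6B, a membrane glycoprotein of neurons and glia, 11.7-fold over testis at 2235 ± 503. MAP2, which binds dendritic microtubules, was 18.7-fold over testis at 1894 ± 413 CPM. SNAP25, of the vesicle fusion machinery, reached 1835 ± 139 CPM, 33.9-fold over heart, and SYT1, the calcium sensor of vesicle release, 1418 ± 363 CPM, 225-fold over testis. The neuronal calcium sensor VSNL1 was 14.4-fold over liver at 1420.2 ± 315 CPM. NELL2 was 4.07-fold over testis at 1558 ± 622 CPM (log2 2.03 ± 0.32), and its log2 difference of 1.98 with the animal as a block no longer met the 4-fold threshold. All 23 measured members of the neuronal list were higher in brain, also when adjusted over the list alone (camera adjusted p = 3.9e-20 and adjusted p = 4.4e-04 with an estimated correlation).

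Glial genes were higher in brain too, with 13 of 15 measured list members higher and 1 lower, the same counts adjusted over the list alone (camera adjusted p = 1.0e-07 and adjusted p = 0.0142 with an estimated correlation). SLC1A3, the other astrocyte glutamate transporter, had 928 ± 207 CPM (SD, n = 5) in brain against 1.31 ± 0.624 in kidney. The myelin gene MBP had 1449.8 ± 1128 CPM, with a wide spread that rests on brain replicate 2. It was 6.86-fold over muscle, and 4.50-fold without brain replicate 2. The gene annotated MOG was the lower member, at 12.0 ± 1.25 CPM in brain and 687 ± 287 in lung (log2 −1.59 ± 0.33 against the mean of the others, adjusted p = 6.0e-05). Among genes abundant elsewhere, the serum protein ALB stood at 4.19 ± 1.76 CPM in brain (log2 −3.40 ± 0.46), the fast myosin heavy chain MYH1E at 1.10 ± 0.236 (log2 −3.66 ± 0.32) and skeletal actin ACTA1 at 1.70 ± 0.318 (log2 −5.53 ± 0.41). In brain replicate 2 the cerebellar gene CBLN1 reached 850 CPM against 3.69 ± 1.85 in the 4 other brain libraries, and CAMK2A lay at 229.7 CPM.

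Heart was marked by cardiomyocyte genes, among them sarcomere genes and the gene of a natriuretic peptide. MYH15, the ventricular myosin heavy chain of birds (chromosome 1, 88760859 to 88807429), was the most abundant elevated gene with 40270.3 ± 7769 CPM (SD, n = 5). It was 876-fold over liver, the next tissue (log2 9.77 ± 0.37, adjusted p = 8.5e-23). The myosin light chains MYL10 and MYL3 reached 16651 ± 5085 and 12981 ± 1478 CPM, with no other tissue above 2.42 ± 0.515 and 0.960 ± 0.175 respectively. Cardiac actin ACTC1 had 16584 ± 3215 CPM, 2051-fold over muscle, and the myosin-binding protein MYBPC3 had 12799.8 ± 1363, 8985-fold over muscle. MYL2, the ventricular regulatory light chain, had 11262 ± 1030.1 CPM and was 5221-fold over testis, or 30455-fold without replicate 5. NPPA, which encodes atrial natriuretic peptide (chromosome 21, 5578197 to 5580816), had 11164 ± 5847 CPM and 1.01 ± 0.393 in lung, the next tissue. Cardiac troponin T, TNNT2, was 6375-fold over muscle at 10532 ± 701 CPM. Myoglobin, MB, was 31.9-fold over muscle at 9329 ± 593 CPM, and the actin ACTBL2L had 5813 ± 1091. All 23 measured cardiomyocyte list members were higher in heart, also adjusted over the list alone (camera adjusted p = 2.8e-42 and adjusted p = 9.9e-08 with an estimated correlation). LDHA, the muscle form of lactate dehydrogenase, lay at 22.4 ± 3.48 CPM in heart, log2 −4.57 ± 0.19 against the mean of the others. Fibrinogen beta, FGB, was lower at 2.98 ± 2.33 CPM (log2 −4.69, or −3.78 without replicate 1), as was the beta-defensin AvBD10 at 1.99 ± 0.474 (log2 −4.05 ± 0.99, or −3.28 without replicate 1).

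Intestine was marked by enterocyte and gut secretory genes, and the immunoglobulin genes IGLL1 and JCHAIN were among its most abundant elevated genes. GUCA2A, which encodes the gut peptide guanylin (chromosome 21, 5836155 to 5841051), had 7273 ± 1589 CPM (SD, n = 5), 172-fold over lung (log2 7.42 ± 1.23, adjusted p = 2.8e-06). The immunoglobulin light chain gene IGLL1 was higher still at 8009.7 ± 2573 CPM, 16.6-fold over lung with 482 ± 449.8 (adjusted p = 0.00627), and JCHAIN, which joins secreted antibodies, had 3299 ± 804 CPM, 21.7-fold over lung. FABP1, a fatty acid binding protein, had 5518 ± 1436 CPM and was 30.4-fold over liver, or 57.0-fold without replicate 4. Sucrase-isomaltase, SI (chromosome 9, 21314645 to 21359399), had 3054 ± 572 CPM, the retinol carrier RBP2 3416 ± 553 and the fatty acid carrier FABP2 3025 ± 288. For these 3 genes muscle was the next tissue, through muscle replicate 3. SI was 515-fold over muscle (10312-fold without replicate 3), RBP2 455-fold (7149-fold) and FABP2 442-fold (11485-fold). The sodium-glucose transporter SLC5A1 was 25-fold over kidney at 2483 ± 455 CPM, and the brush border enzyme MGAM was 142-fold over lung at 1805 ± 322 CPM. Of 31 measured enterocyte and gut secretory list members, 28 were higher in intestine and none lower, also adjusted over the list alone (camera adjusted p = 2.4e-18 and adjusted p = 0.00705 with an estimated correlation). PIGR, which carries antibodies across epithelia, was above the mean of the others by log2 7.82 ± 0.55 (8.53 without replicate 1), with 2567 ± 457 CPM in intestine and 3857 ± 408 in liver. Pancreatic amylase, AMY2A, met the elevated threshold with 1886 ± 4206 CPM, 78.2-fold over lung (137-fold without replicate 4), but intestine replicate 1 alone held 9409 CPM. Without that replicate in all tissues it was log2 −2.11 against lung. The muscle genes MYH1E, ACTA1 and MYL1 were lower in intestine than the mean of the others, at 1.33 ± 0.484, 4.28 ± 1.92 and 0.404 ± 0.247 CPM.

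Kidney was marked by tubule transport genes, and the genes AvBD10 and PCK1 were its most abundant elevated ones with a symbol. The most abundant elevated gene was AvBD10, a beta-defensin (chromosome 3, 107427133 to 107429773), with 26443 ± 2017 CPM (SD, n = 5), 20.5-fold over liver with 1287 ± 285 (log2 4.36 ± 1.04, adjusted p = 5.4e-04). PCK1, the cytosolic enzyme that commits carbon to glucose synthesis, had 9489 ± 3471 CPM and was 34.5-fold over liver, or 73.3-fold without replicate 1. LRP2, the endocytic receptor megalin of the proximal tubule (chromosome 7, 18735085 to 18844135), had 2916 ± 364 CPM, 51.1-fold over testis, and its partner CUBN had 1191 ± 195, 44.8-fold over intestine. The phosphate transporter SLC34A1 had 1585 ± 430.0 CPM, 215-fold over intestine or 10519-fold without replicate 1, whose intestine library held most of the intestine counts of this gene. AVDL and MUC4L, at 2334 ± 523 and 2098 ± 469.8 CPM, showed the same: 243-fold and 189-fold over intestine, or 12793-fold and 5709-fold without replicate 1. Over liver, with all libraries, AVDL was 395-fold and MUC4L 1467-fold higher. The dicarboxylate transporter SLC13A3 was 14.3-fold over brain at 1357 ± 364 CPM, and the potassium channel KCNJ16 was 38.5-fold over intestine at 1366 ± 159. ACSM4L, an acyl-CoA synthetase, was 52.1-fold over muscle at 1495 ± 209 CPM, and NDRG1 was 4.78-fold over lung at 1902 ± 507. Ethanolamine kinase, ETNK1, was 4.01-fold over intestine at 2929.8 ± 357 CPM, at the edge of the threshold (log2 2.00 ± 0.17), and without replicate 2 its log2 difference of 1.95 no longer met it.

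Of 24 measured kidney tubule transport list members, 22 were higher in kidney and 1 lower, the same counts adjusted over the list alone (camera adjusted p = 5.7e-18 and adjusted p = 8.0e-04 with an estimated correlation). The lower one was the water channel AQP1, with 4.13 ± 2.07 CPM in kidney and 286 ± 94.4 in lung (log2 −2.08 ± 0.36 against the mean of the others, adjusted p = 5.6e-06). Of 17 glomerulus and kidney development list members, 16 were higher and none lower, also adjusted over the list alone (camera adjusted p = 5.3e-16 and adjusted p = 0.00355 with an estimated correlation). PAX2, a transcription factor of kidney development, had 259 ± 61.0 CPM (SD, n = 5), log2 9.49 above the mean of the others (10.13 without replicate 2). KL, a hormone co-receptor, had 195 ± 34 CPM, 6.29-fold over muscle. PODXL, a coat protein of glomerular podocytes, had 245 ± 17.5 CPM and more in lung, 519.7 ± 101. The muscle genes MYH1E, TNNT3 and MYL1 were lower in kidney than the mean of the others by log2 −3.43 ± 0.31, −3.14 ± 0.30 and −3.93 ± 0.35. In kidney replicate 3, smooth muscle list genes lay at a mean log2 CPM of 5.74, against 4.04 in the other 4 kidney libraries.

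Liver was marked by secreted proteins of hepatocytes and by hepatocyte metabolic enzymes. Albumin, ALB (chromosome 4, 50805767 to 50848889), took the largest level of any elevated gene, 184639 ± 17928 CPM (SD, n = 5), 11124-fold over testis (log2 13.44 ± 0.76, adjusted p = 4.3e-18). The 3 fibrinogen chains, neighbours on chromosome 4 from 20308924 to 20338478, were next: FGB had 35148 ± 8718 CPM, FGA 32963 ± 7046 and FGG 27594 ± 5551. FGB was 76.6-fold over kidney, FGA 1371-fold over kidney and FGG 1607-fold over testis. PIT54, the haemoglobin-binding plasma protein of birds, had 26179 ± 7464 CPM and was 11541-fold over muscle, or 50216-fold without replicate 4. The protease inhibitor SPIK5 had 26162 ± 4688 CPM and transferrin, TF, 19964 ± 1572, with lung the next tissue through lung replicate 1. SPIK5 was 73.3-fold over lung (991-fold without replicate 1) and TF 14.9-fold (119-fold without replicate 1). Over kidney, with all libraries, SPIK5 was 279-fold and TF 165-fold higher. Haemopexin, HPX, was 148.5-fold over lung at 15097 ± 3656 CPM, the beta-defensin AvBD9 14.6-fold over kidney at 11447 ± 3084, and phosphoserine phosphatase, PSPH, 27.3-fold over kidney at 11174 ± 1883. All 30 measured members of the hepatocyte secreted protein list were higher in liver, also adjusted over the list alone (camera adjusted p = 4.6e-37 and adjusted p = 3.3e-05 with an estimated correlation).

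Of 20 measured hepatocyte metabolic enzymes, 19 were higher in liver and 1 lower, the same counts adjusted over the list alone (camera adjusted p = 5.8e-19 and adjusted p = 2.6e-05 with an estimated correlation). The tyrosine-degrading enzymes TAT and HPD had 3921 ± 807 and 3087 ± 637 CPM (SD, n = 5), 354-fold over testis and 35.5-fold over kidney. TDO2, which opens the tryptophan ring, had 2201 ± 511 CPM, 152-fold over heart. The lower member was ARG2, a mitochondrial arginase, with 1.96 ± 0.458 CPM in liver against 161 ± 80.7 in kidney (log2 −2.49 ± 0.30 against the mean of the others). The same list was higher in kidney, with 15 members higher and 3 lower (camera adjusted p = 8.4e-10 and adjusted p = 8.0e-04 with an estimated correlation). Pyruvate kinase PKM lay at 31.6 ± 4.57 CPM in liver, log2 −4.30 ± 0.19 against the mean of the others, and ACTA1 and TNNT3 at 2.56 ± 0.672 and 1.92 ± 0.471.

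Lung was marked by epithelial genes, among them surfactant genes, and by mesenchyme and endothelium genes. Cystatin C, CST3, a protease inhibitor, was the most abundant elevated gene at 15765 ± 5418 CPM (SD, n = 5), 17.7-fold over heart with 890.5 ± 113 (log2 4.15 ± 0.19, adjusted p = 2.6e-20). The matrix gene TNXB had 8144 ± 3325 CPM and was 1897-fold over heart, or 6008-fold without replicate 1. Adult haemoglobin chains HBBA and HBA1 had 3208 ± 1598 and 2111 ± 1113 CPM, 7.04-fold and 7.59-fold over heart. The goose-type lysozyme LYG2 was 133-fold over intestine at 3037 ± 516 CPM. Surfactant protein C, SFTPC (chromosome 22, 60649 to 62142), had 942 ± 313 CPM, 429.6-fold over brain. The surfactant proteins SFTPA2 and SFTPA1 had 2557 ± 1088 and 1397 ± 435 CPM, with kidney the next tissue through kidney replicate 3: 46.4-fold and 17.9-fold over kidney, or 183-fold and 717-fold without replicate 3. Of 15 measured lung epithelium list members, 13 were higher and none lower, also adjusted over the list alone (camera adjusted p = 2.8e-09 and adjusted p = 0.0144 with an estimated correlation). CLDN18, an airway tight junction gene, had 521 ± 181 CPM, log2 12.32 above the mean of the others (12.93 without replicate 3). Of 19 mesenchyme and endothelium list members, 18 were higher in lung, also adjusted over the list alone (camera adjusted p = 1.1e-18 and adjusted p = 0.00559 with an estimated correlation).

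Endothelial genes of lung were also expressed in heart. PECAM1, an endothelial adhesion gene, had 1176 ± 518 CPM (SD, n = 5) in lung and 425 ± 201 in heart, VWF of blood clotting 432 ± 179 and 385 ± 83.4, and the junction gene CDH5 309 ± 123 and 142 ± 36.3. CLDN5, a tight junction gene of vessels, had 177 ± 68.2 CPM in lung, 7.19-fold over brain. The difference between lung and heart passed the test for PECAM1 (adjusted p = 0.00174) and CDH5 (adjusted p = 1.3e-04) and not for VWF (adjusted p = 0.573). GAPDH and APOA1 were lower in lung than the mean of the others, by log2 −3.94 ± 0.16 and −3.16 ± 0.32, and MYH1E lay at 0.966 ± 0.422 CPM. A pair of neighbours on chromosome 5, INCENP (17337653 to 17361557) and TPCN2 (17367707 to 17391753), met the elevated threshold through lung replicate 1 alone. INCENP, of the mitotic chromosome passenger complex, had 1923 ± 4239 CPM in lung with 9506 in that library, log2 2.62 ± 1.10 over testis (adjusted p = 0.0287). Its log2 difference was −3.48 without lung replicate 1, and 0.95 with the animal as a block (adjusted p = 0.514). TPCN2, an endolysosomal channel, had 1195 ± 2546 CPM with 5749.5 in that library, log2 3.47 ± 0.84 over intestine, or −0.93 without lung replicate 1. Both are among the 221 genes elevated in lung.

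Muscle was marked by fast skeletal muscle genes, and GAPDH, LDHA and PKM were among its most abundant elevated genes. The fast myosin heavy chain MYH1E (chromosome 18, 564255 to 586932) had 141788 ± 20279 CPM (SD, n = 5), 7038-fold over testis (log2 12.78 ± 0.49, adjusted p = 3.2e-23). GAPDH, the glycolytic dehydrogenase, was the second most abundant at 123326 ± 6913 CPM, 29.6-fold over heart, and skeletal actin ACTA1 (chromosome 3, 40088178 to 40090517) had 102309 ± 12305, 89.4-fold over heart. Fast troponin T, TNNT3, had 51469.6 ± 4339 CPM, 2319-fold over testis, and fast troponin C, TNNC2, had 20537 ± 1201, 10123-fold over heart. Tropomyosin TPM1 was 99-fold over intestine at 46956 ± 4193 CPM, the myosin light chain MYL1 3085-fold over heart at 33315 ± 3366 and the nebulin gene NEBL1 396-fold over testis at 29558 ± 5142. LDHA was 24.2-fold over intestine at 33937 ± 3451 CPM and PKM 43.7-fold over brain at 32665 ± 3899. All 19 measured fast skeletal muscle list members were higher in muscle, also adjusted over the list alone (camera adjusted p = 4.3e-22 and adjusted p = 2.7e-06 with an estimated correlation). MYH15 was lower in muscle by log2 −5.05 ± 0.29, at 1.90 ± 0.498 CPM. FGB was lower by log2 −3.53 ± 0.96 (−2.62 without replicate 1 and −4.70 without replicate 4) and SPIK5 by log2 −3.03 ± 1.15 (−2.10 without replicate 3 and −4.12 without replicate 4). In muscle replicate 3 the intestine gene FABP2 lay at 33.1 CPM, against 0.260 in the 4 other muscle libraries.

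Testis was marked by meiosis and germ line genes. TUBB4B, a tubulin of cilia and flagella (chromosome 17, 2241348 to 2243444), had 3703 ± 349 CPM (SD, n = 5), 7.72-fold over brain (log2 2.95 ± 0.26, adjusted p = 8.8e-13). The myotubularin-related gene MTMR9 had 1806 ± 101 CPM, 12.6-fold over brain. HK3, a hexokinase, and SLC2A14, a glucose transporter, had 1347 ± 163 and 1225 ± 99.7 CPM, 74.5-fold over heart and 17.5-fold over brain. The microtubule genes KIF2B, TUBA8B and TPPP2 had 1114 ± 113, 1107 ± 144 and 1058 ± 125 CPM, and were 165-fold, 172-fold and, over liver for TPPP2, 146-fold higher than in the next tissue. PLCZ1, the sperm phospholipase that activates the egg, was 242-fold over muscle at 976 ± 78.6 CPM. DNAH8, an axonemal dynein, was 416-fold over kidney (697-fold without replicate 1) at 906 ± 80.4 CPM, and ACSBG2, an acyl-CoA synthetase, 5.66-fold over liver (14.6-fold without replicate 1) at 895 ± 89.1. Of 28 measured meiosis and germ line list members, 26 were higher and none lower, also adjusted over the list alone (camera adjusted p = 1.1e-10 and adjusted p = 0.00206 with an estimated correlation). RNF17, of the germ cell small RNA machinery, had 689 ± 48.0 CPM, the meiotic regulator BOLL 438 ± 30.6, PIWIL1, which binds piRNAs, 343 ± 19.6 and STK31 287 ± 34.3.

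Of 25 spermatid and sperm list members, 24 were higher in testis and 1 lower, the same counts adjusted over the list alone (camera adjusted p = 3.3e-09 and adjusted p = 0.0866 with an estimated correlation). ODF2, of the sperm tail's outer dense fibres, had 639.9 ± 28.2 CPM (SD, n = 5), 22.3-fold over intestine, and the chaperone DNAJB8 had 514 ± 58.4, 134-fold over muscle. The lower member was the chaperone HSPA2, with 300.2 ± 47.4 CPM in testis and 3940.2 ± 1317 in lung (log2 −1.28 ± 0.22 against the mean of the others). Genes of the somatic Sertoli and Leydig cells were mixed, with 15 of 21 higher and 4 lower, the same counts adjusted over the list alone (camera adjusted p = 0.0217 and adjusted p = 0.136 with an estimated correlation). AMH, the Sertoli cell hormone, had 86.3 ± 20.5 CPM in testis and 127 ± 16.9 in muscle, CLDN11, of the blood-testis barrier, 57.9 ± 8.48, and CYP17A1, of androgen synthesis, 30.4 ± 16.1. DMRT1, the Z-linked sex determination gene (25949702 to 25952032), had 19.6 ± 3.05 CPM, 38.1-fold over kidney. Lower members included the germ cell growth factor KITLG (log2 −2.80 ± 0.30) and INHBA, an activin subunit (log2 −2.69 ± 0.49). TPM1 and APOA1 were lower by log2 −4.21 ± 0.18 and −4.82 ± 0.36, and AvBD10 by −3.90 ± 0.95 (−2.82 without replicate 1 and −5.41 without replicate 4).

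Heart and muscle, both striated, used different genes for the same sarcomere parts. In heart 5086 genes were higher and 3509 lower than in muscle. Heart held MYH15 at a level 21279-fold over muscle (log2 14.38 ± 0.44, adjusted p = 3.0e-25), and muscle held MYH1E at a level 12262-fold over heart, which had 11.5 ± 8.73 CPM (SD, n = 5). The light chains MYL3, MYL2 and MYL10 were 27250.1-fold, 23438-fold and 22979-fold higher in heart, the last one 35432-fold without muscle replicate 2. MYL1 was 3085-fold higher in muscle. Troponin T was TNNT2 in heart, 6375-fold higher, and TNNT3 in muscle, 7139-fold higher. The actin was ACTC1 in heart, 2051-fold higher, and ACTA1 in muscle, 89.4-fold higher. MYBPC3 and NPPA were 8985-fold and 21096-fold higher in heart. In muscle MYL3 had 0.463 CPM, MYL2 0.475, MYL10 0.750 and NPPA 0.526. These levels are near the floor of up to 0.277 CPM, so the folds of these genes are imprecise. Tropomyosin TPM1 was 709.6-fold higher in muscle. The glycolytic genes LDHA, PKM and GAPDH were 1519-fold, 49.3-fold and 29.6-fold higher in muscle.

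Between liver and kidney, the plasma protein genes ALB and FGG were higher in liver, and the endocytic receptor LRP2 and the defensin AvBD10 were higher in kidney. In liver 2859 genes were higher and 4043 lower than in kidney. ALB was 18032-fold higher in liver (log2 14.14 ± 0.77, adjusted p = 9.1e-18) and FGG 35467-fold, with 0.766 ± 0.240 CPM (SD, n = 5) in kidney. PIT54 was 86983-fold higher in liver, with 0.293 ± 0.0736 CPM in kidney, FGA 1371-fold, FGB 76.6-fold and TF 165-fold. SPIK5 was 279-fold higher in liver, or 9571-fold without kidney replicate 3. The lipoprotein gene APOA1 had 19686 ± 5012 CPM in liver and 2525 ± 737 in kidney, a 7.80-fold difference. Kidney had higher LRP2 (505-fold), ETNK1 (20.6-fold, log2 −4.36 ± 0.19 for liver minus kidney) and NDRG1 (5.73-fold). AvBD10 was 20.5-fold higher in kidney, PCK1 34.5-fold (67.4-fold without liver replicate 1), AVDL 395-fold (611-fold without replicate 3) and MUC4L 1467-fold (6005-fold without liver replicate 3).

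Testis and brain, the tissues with the most elevated genes, were the third pair. In testis 6681 genes were higher and 5897 lower than in brain. The RNA-binding genes YBX1 and PABPC1 had 1639.8 ± 76.3 and 1352 ± 73.9 CPM (SD, n = 5) in testis, 14.5-fold and 7.99-fold over brain (adjusted p = 6.2e-26 and 1.0e-23). DPYS, of pyrimidine breakdown, had 1425 ± 92.2 CPM in testis and 0.282 ± 0.301 in brain, a 4996-fold difference (9145-fold without brain replicate 2). KIF2B was 3884-fold higher in testis (6249-fold without brain replicate 2), with 0.275 ± 0.273 CPM in brain. HK3 was 101-fold higher in testis, SLC2A14 17.5-fold, MTMR9 12.6-fold and TUBB4B 7.72-fold. YWHAG, a 14-3-3 protein, was 94.6-fold higher in brain at 2333 ± 551 CPM, and the lysosomal gene PSAP 5.43-fold at 3158 ± 189. CAMK2A and SLC1A2 were 178-fold and 347-fold higher in brain, CLSTN1 20.8-fold, MAP2 18.7-fold and GPM6B 11.7-fold.

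Oxidative phosphorylation genes were higher in heart and lower in lung. Of 35 measured oxidative phosphorylation genes, 34 were higher in heart and 34 were lower in lung, the same counts adjusted over the list alone (camera adjusted p = 2.3e-40 and 1.9e-31, and adjusted p = 0.00705 and 0.0252 with an estimated correlation). ATP5F1B, of ATP synthase, had 2938 ± 57.3 CPM (SD, n = 5) in heart and 2404 ± 274 in muscle, and in heart the respiratory genes COX4I1 and CYCS had 1666 ± 135 and 1080.1 ± 102. In muscle 33 were higher and 1 lower (camera adjusted p = 4.4e-18 and adjusted p = 0.112 with an estimated correlation), in testis 22 were lower (1.7e-08 and adjusted p = 0.384 with an estimated correlation) and in brain 11 were lower and 1 higher (1.5e-07 and adjusted p = 0.415 with an estimated correlation). The list did not pass in intestine, kidney or liver. Glycolysis genes were lower in lung, 13 of 17 with 1 higher, the same counts adjusted over the list alone (camera adjusted p = 2.8e-10 and adjusted p = 0.0104 with an estimated correlation). ENO1 had 357 ± 67.3 CPM in lung and 4727 ± 215 in liver, while HK2 was the higher member at 236 ± 171. In muscle 10 glycolysis genes were higher and 6 lower (camera adjusted p = 9.2e-06 and adjusted p = 0.125 with an estimated correlation), and in intestine 6 were lower and 2 higher (0.0456 and adjusted p = 0.577 with an estimated correlation). The call in intestine also ended without the 7 doubted libraries (camera adjusted p = 0.0697) and without replicate 1, 3 or 4 (0.0535, 0.0978 and 0.0568). Genes of purine synthesis and uric acid formation, the route by which birds excrete nitrogen, were higher in liver, 9 of 15 with 3 lower, the same counts adjusted over the list alone (camera adjusted p = 9.2e-06 and adjusted p = 4.1e-04 with an estimated correlation). In lung 5 were lower and 1 higher (camera adjusted p = 0.0288 and adjusted p = 0.0828 with an estimated correlation). ATIC had 6038 ± 1118 CPM in liver and 86.0 ± 5.63 in kidney, the next tissue, PAICS 2272 ± 888, and XDH, which forms uric acid, 2665 ± 1105 against 485 ± 90.9 in kidney. Of the 184 list tests, 82 passed at the preset correlation, 84 at that correlation with the animal as a block, and 22 with an estimated correlation.

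Genes elevated in testis lay on the Z chromosome more often than other genes, in these birds with a pair of Z chromosomes. Of 2150 testis-elevated genes with a known chromosome, 226 (10.5%) were on Z, against 4.56% of the other tested genes (odds ratio 2.46, 95% interval 2.10 to 2.88, Fisher's exact p = 4.7e-26, two-sided, adjusted p = 3.7e-25 over 8 tissues). In the other 7 tissues the adjusted p lay between 0.151 and 0.897. The Z-linked testis genes with a symbol included the germ cell helicase DDX4 (16929379 to 16960987), with 192 ± 11.8 CPM (SD, n = 5) in testis and 0.558 ± 0.502 in muscle, the next tissue. EMB, KIF27, ELL2 and KIF24 had 428 ± 41.2, 402 ± 26.3, 355 ± 11.7 and 347 ± 24.1 CPM. IFT74, of ciliary transport, had 234 ± 26.1 CPM, the condensin gene SMC2 233 ± 6.56 and CEP78, of centrosomes, 208 ± 4.13. EMB, KIF27, ELL2, KIF24, IFT74, SMC2, CEP78 and DDX4 were chosen after their values were seen. Among genes without a symbol, 173 of 1236 elevated genes lay on Z (odds ratio 3.54). Among genes with a symbol, 53 of 914 lay on Z (odds ratio 1.27, 95% interval 0.936 to 1.71, Fisher's exact p = 0.105). With elevated neighbours within 100 kb counted once, 107 of 1318 did (odds ratio 1.85, Fisher's exact p = 7.1e-08).

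**Figure D3:**
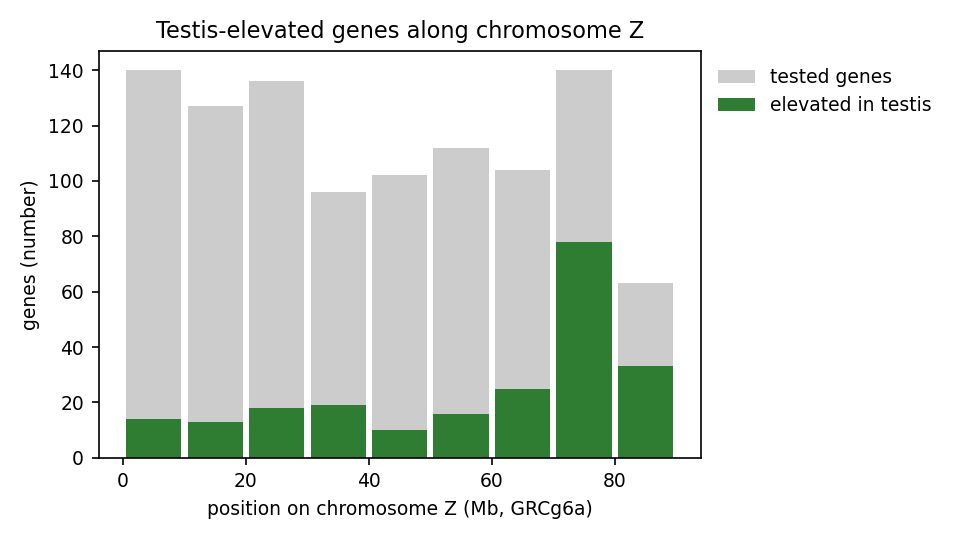
Numbers of tested Z genes and of those elevated in testis, in bins of 10 Mb along chromosome Z (GRCg6a), as bars. The bin from 70 to 80 Mb holds 78 elevated of 140 tested genes and the bin from 80 to 90 Mb 33 of 63, above every other bin.

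Genes of the immune region on chromosome 16 were prominent among those that differed between the 5 roosters across tissues. MICA, an MHC class I-like gene (2069079 to 2114384), was high in animals 1, 2 and 3, with mean log2 deviations of 2.32, 2.27 and 3.14 over the 8 tissues, and low in animals 4 and 5, with −3.89 and −3.84 (range 7.04, adjusted p = 1.1e-17). HLA-F10AL1, another class I-like gene, ranged over log2 4.76 and ZNFY4 over 2.97, in both cases highest in animal 3. CLC2BL1, a lectin-like gene on chromosome 16, was lowest in animal 4 by log2 −1.90. COMTD1 on chromosome 6, a predicted methyltransferase, was highest in animal 5 by log2 1.51 (adjusted p = 7.1e-13, and 0.786 with animal 5 left out), and CD69L on chromosome 1 ranged over 2.03. MICA and HLA-F10AL1 share exon bases with other genes and are uncertain. In the test of animals with tissue as a term, 3098 of 19864 genes (15.6%) differed, and animal 5 was the most extreme in 1637 of them. Replicate 5 also had the most counts in each of the 8 tissues, so its animal and its sequencing depth were not separate. With counts thinned to equal library totals 2770 genes differed, 1454 of them most extreme in animal 5, and with animal 5 left out 758 genes differed. The number of genes differing between animals was 1696 without the intestine libraries, 1708 without kidney and 1881 without liver. On chromosome 16, which carries the chicken major histocompatibility complex, 65 of 151 genes did (43%), against 15.4% elsewhere (odds ratio 4.16, 95% interval 2.96 to 5.82, Fisher's exact p = 6.7e-16, two-sided). This test counts genes as independent. The chromosome 16 genes are neighbours compared in the same 5 animals, and some share exon bases, so its p and interval overstate the certainty. A version with neighbours counted once was not run. Most differences were small: the median range between animals was log2 0.615, and 744 of the 3098 genes ranged over more than 1.

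**Figure D4:**
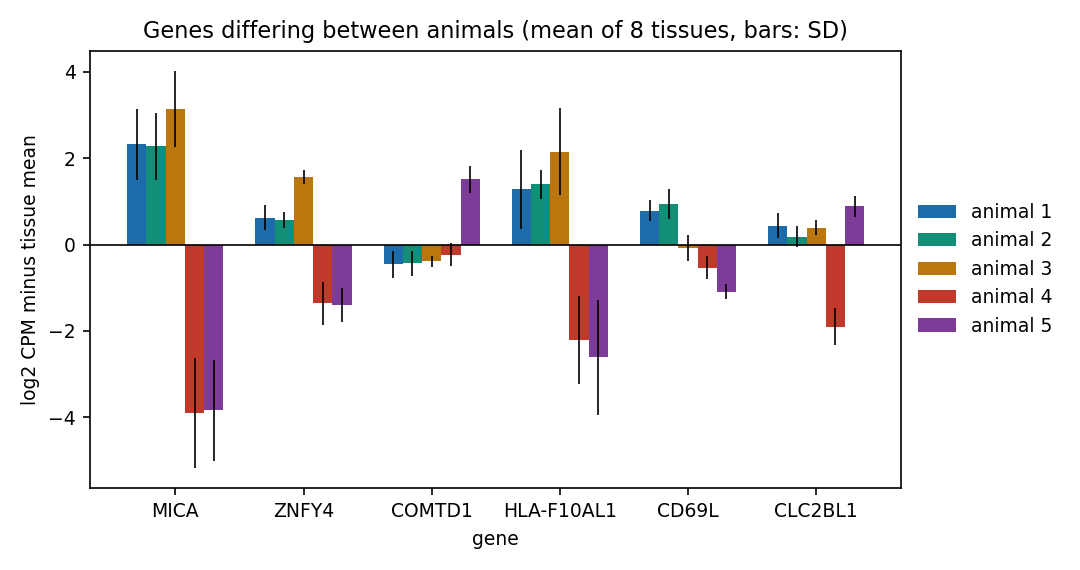
Mean log2 deviation of each of the 5 animals from the tissue means, over 8 tissues with SD as bars, for the 6 named genes that differed between animals. MICA separates animals 1, 2 and 3 (2.32, 2.27 and 3.14) from animals 4 and 5 (−3.89 and −3.84).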

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

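The tests on muscle replicate 3, brain replicate 2 and the animal labels were chosen after these results were seen, and so was the bound on cross-talk. A library was listed when a gene list's mean or a named gene lay far from the other 4 libraries of its tissue. This gave 21 cases in 196 groups scanned, 10 of 86 lists and 11 of 110 genes, where chance alone gives about 1 in 20 groups, or 9.8.

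Muscle replicate 3 held intestinal transcripts: 87 of 110 genes elevated 10-fold in intestine, at 50 CPM or more (79.1%), were higher there than in each other muscle library. FABP2 had 33.1 CPM against 0.260 in the 4 others and 3025 in intestine. A small amount of intestine RNA may explain this, since the excess rose with the intestine level over these genes (Spearman rho 0.614 across genes, which are not independent replicates) with a median share of 1.01% (5% to 95% of genes −0.135 to 2.00). An exchange of the muscle and intestine libraries of animal 3 goes against the correlations, as muscle replicate 3 had r = 0.968 with muscle and 0.753 with intestine, a difference of 0.215, and intestine replicate 3 had 0.981 and 0.737. Cross-talk from all libraries of a run would bring liver genes too, but their share was −0.0129%, with kidney at −0.0112%, lung −0.00501% and heart −0.00531%; the testis share of 0.656% stays open, as testis genes also had 0.747% of their testis level in muscle replicate 4 and 0.780% in replicate 5, against 1.26% in replicate 3.

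Brain replicate 2 held a different set of regional genes. A different region of the brain in the sample may explain this: 17 of 20 cerebellum genes were raised over 2-fold, with a median log2 shift of 2.83, and 21 of 22 forebrain genes lowered, with a median of −3.95. CBLN1 had 849.9 CPM against 3.69 ± 1.85 in the 4 other brain libraries, PVALB 682 against 115 ± 65.3 and ETV1 580.2 against 149 ± 47.1, but GRM4, another cerebellum gene, was lower, with 7.83 against 101 (log2 −3.65). ARPP21 had 311 CPM against 1276 ± 186 and MEIS2 51.2 against 121 ± 23.3, while SLC17A6, the forebrain gene not lowered over 2-fold, whose brain level had been seen before, had 796 against a mean of 1070. RNA of another tissue goes against 94.1% of the measured raised cerebellum genes, 16 of 17, which were lower in each of the 7 other tissues than in brain replicate 2.

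Kidney replicate 2, testis replicate 1 and testis replicate 2 carry different animal numbers in their titles and individual fields. The individual field as the true number goes against the correlations with other tissues, which were higher with the title's animal in all 3 libraries. With the title's number kidney replicate 2 had a mean r of 0.154 and with the other number −0.0281, testis replicate 1 had 0.0760 and −0.0195, and testis replicate 2 had 0.118 and 0.000195. The largest of the 3 differences was 0.182. The title's number may be the right one, since no other animal had a higher correlation, the closest lying at a difference of −0.0546 from the title's animal in testis replicate 1.

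In brain replicate 2, CAMK2A lay at log2 CPM 7.84 against a mean of 11.76 in the 4 others, SLC1A2 at 10.20 against 11.51, MAP2 at 10.22 against 11.01 and NELL2 at 8.85 against 10.84. Motile cilia genes lay at a mean of 1.51 against 2.83 ± 0.179 in that library and purine genes at 3.32 against 3.84 ± 0.0332. In brain replicate 1, fibroblast genes lay at 2.56 against 3.13 ± 0.0741. MYL2 in heart replicate 5 lay at 13.21 against 13.51. In intestine replicate 1 AMY2A lay at 13.20 against 2.37, and in intestine replicate 5 fibroblast genes at 6.46 against 5.98. Kidney replicate 3 had leukocyte genes at 2.63 against 3.93 and smooth muscle genes at 5.74 against 4.04. FGG in liver replicate 2 lay at 14.14 against 14.87, and HPD in liver replicate 4 at 10.98 against 11.71. Lung replicate 1 had motile cilia genes at 4.15 against 0.38 and TPCN2 at 12.49 against 5.74. Oxidative phosphorylation genes lay at 8.39 against 8.22 in muscle replicate 2, and glycolysis genes at 9.73 against 9.30 in muscle replicate 3 and 6.67 against 6.81 in testis replicate 4. In testis replicate 5, PLCZ1 lay at 10.12 against 9.88 and DNAH8 at 10.03 against 9.77.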

How the results depend on the processing

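Of the alternative values of counts and shares, 829 kept their direction and side of the threshold or stayed within 1.5-fold, 42 moved, 1 became stronger and 1 weaker; for genes the numbers were 4800 the same, 30 weaker and 9 reversed, for lists 807 the same and 95 weaker, 60 of these with an estimated correlation, and for animal genes 89 the same and 1 weaker. Without the 7 doubted libraries, elevated genes numbered 1085 in brain, 213 in heart, 366 in intestine, 351 in kidney, 400 in liver, 230 in lung, 402 in muscle and 2393 in testis. At 2-fold, elevated genes numbered 1628 in brain, 399 in heart, 725 in intestine, 518 in kidney, 748 in liver, 556 in lung and 1155 in muscle, and at 10-fold 552, 95, 202, 169, 209, 50 and 168, with 1353 in testis, by construction of the threshold. With glmTreat, elevated genes numbered 232 in intestine, 200 in kidney and 85 in lung, where the test asks for more than a 4-fold change. Lower genes numbered 1297 in kidney and 2243 in lung, where it asks for more than a 2-fold change. The number of genes differing between animals was 1696 without the intestine libraries, 1708 without kidney and 1881 without liver, against 2078 without lung, 2191 without heart, 2883 without brain, 2949 without muscle and 3491 without testis, which each leave out as many libraries; the cause was not tested. For genes differing between animals the number was 758 with animal 5 left out and 2770 with counts thinned to equal library totals, and COMTD1 between animals was not called with animal 5 left out (adjusted p = 0.786). List tests past the threshold numbered 22 with an estimated correlation and 145 with fry, which tests another hypothesis. Some list calls, glycolysis in intestine among them, also ended when 1 replicate number was left out. The single most abundant gene took 1.11% of counts in brain, 3.57% in heart, 1.42% in intestine, 3.14% in kidney, 11.8% in liver, 2.59% in lung, 6.61% in muscle and 0.599% in testis, and the top 100 genes 17.3%, 34.1%, 23.4%, 24.4%, 47.9%, 23.6%, 52.8% and 13.2%. For the Z-linked share of elevated genes in liver the odds ratio at 10-fold was 0.265 (Fisher's exact adjusted p = 0.0427, with a range up to 0.650 over its alternatives). For the Z-linked share of elevated genes in testis it was 1.27 over genes with a symbol (Fisher's exact p = 0.105). Over all genes with no filter the testis share had a Fisher's exact adjusted p of 6.6e-35, and genes with a symbol were not tested without the filter. The cause was not tested. AMY2A in intestine over lung was log2 −2.11 without the 7 doubted libraries, −2.11 without replicate 1 and −2.23 without intestine replicate 1 (7.09 without replicate 4), INCENP in lung over testis −3.48, −3.50 and, without lung replicate 1, −3.48 (3.02 without replicate 2), and TPCN2 in lung over intestine −0.87, −0.87 and −0.93 in the same order (3.90 without replicate 3), since 1 library held most of the counts of each. With RLE normalization the median of all genes shifted by log2 0.21 in testis, and with upper quartile by −0.15 in brain, 0.20 in lung and 0.15 in testis. NELL2 in brain over testis was log2 1.98 with the animal as a block, 1.87 with RLE and 1.76 with upper quartile, and ETNK1 in kidney over intestine 1.99 with RLE, each below 4-fold. Depth limits genes near 0.0551 to 0.277 CPM.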

Other observations

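Lists of blood, immune and connective tissue genes were also compared between tissues; of the values in this part, only the pancreas list and the Z bins were chosen after the data were seen. Leukocyte genes were higher in intestine, 23 of 25 (camera adjusted p = 8.4e-10 and adjusted p = 0.270 with an estimated correlation), and in liver, 22 of 25 (6.0e-09 and adjusted p = 0.299 with an estimated correlation). In lung 12 were higher (camera adjusted p = 0.00169 and adjusted p = 0.646 with an estimated correlation). For each list in this part the counts were the same adjusted over the list alone. In intestine CD74, which guides antigen presentation, had 2757 ± 439.9 CPM (SD, n = 5), and the class II genes BLB2 and BLB1 had 323 ± 186 and 259.6 ± 58.5. Leukocyte genes were lower in muscle, 24 (camera adjusted p = 2.9e-04 and adjusted p = 0.619 with an estimated correlation), in testis, 18 with 1 higher (6.5e-04 and adjusted p = 0.643 with an estimated correlation), in brain, 15 with 2 higher (0.00972 and adjusted p = 0.715 with an estimated correlation), and in heart, 7 (0.0203 and adjusted p = 0.715 with an estimated correlation). Smooth muscle genes were higher in lung, 11 of 15 (camera adjusted p = 4.3e-05 and adjusted p = 0.361 with an estimated correlation). They were also higher in intestine, 10 with 1 lower (0.0299 and adjusted p = 0.657 with an estimated correlation), and in heart, 5 with 2 lower (0.00819 and adjusted p = 0.599 with an estimated correlation), and lower in brain, 13 (1.9e-04 and adjusted p = 0.401 with an estimated correlation), and in testis, 12 (0.00852 and adjusted p = 0.621 with an estimated correlation). Among them MYH11, the smooth muscle myosin, had 698 ± 375 CPM in lung and 556 ± 107 in intestine, CALD1 477 ± 200.2 in lung and the actin ACTA2 286 ± 136. Fibroblast and matrix genes were higher in heart, 11 of 17 (camera adjusted p = 6.9e-04 and adjusted p = 0.401 with an estimated correlation), where the matrix genes MGP, DCN and COL3A1 had 257 ± 66.1, 228 ± 45.4 and 218 ± 69.1 CPM. The list was also higher in intestine, 10 of 17 (0.00111 and adjusted p = 0.401 with an estimated correlation), and in lung, 10 of 17 (0.00591 and adjusted p = 0.577 with an estimated correlation), and lower in brain, 12 with 2 higher (0.00143 and adjusted p = 0.480 with an estimated correlation), and in testis, 10 with 1 higher (0.0493 and adjusted p = 0.669 with an estimated correlation). MGP had 421 ± 125 CPM in lung, DCN 233 ± 77.2 in lung and COL3A1 447 ± 142 in intestine, where it was higher than in heart (adjusted p = 0.00292). COL3A1 in heart lay log2 1.10 ± 0.21 above the mean of the others, and 0.88 without heart replicate 5, which ends its call.

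Red cell genes were higher in lung, 13 of 13 (camera adjusted p = 5.3e-10 and adjusted p = 0.136 with an estimated correlation), with HBM at 596 ± 314 CPM (SD, n = 5) there and 78.4 ± 40.7 in heart. They were lower in intestine, 10 (camera adjusted p = 0.00794 and adjusted p = 0.607 with an estimated correlation), and in testis, 9 with 1 higher (0.0198 and adjusted p = 0.643 with an estimated correlation). Adipocyte genes were higher in intestine, 5 of 9 (camera adjusted p = 0.0303 and adjusted p = 0.136 with an estimated correlation), and lower in brain, 7 (0.0382 and adjusted p = 0.176 with an estimated correlation). The lipid droplet genes CIDEC and CIDEA had 164 ± 75.8 and 98.3 ± 33.7 CPM in intestine, and the lipase gene PNPLA2 245 ± 30 there and 1470.4 ± 703 in heart. Genes of motile cilia were higher in testis, 19 of 20 (camera adjusted p = 1.0e-05 and adjusted p = 0.401 with an estimated correlation), with CCDC40 at 398 ± 27.5 CPM, TEKT2 at 354 ± 27.2 and HYDIN at 293 ± 30.8. They were lower in heart, 16 with 1 higher (camera adjusted p = 0.0391 and adjusted p = 0.715 with an estimated correlation), and in intestine, 15 with 2 higher (0.0399 and adjusted p = 0.715 with an estimated correlation). The lung mesenchyme and endothelium list was also higher in heart, 15 of 19 with 1 lower (camera adjusted p = 4.0e-05 and adjusted p = 0.176 with an estimated correlation), and lower in testis, 14 with 2 higher (0.00104 and adjusted p = 0.290 with an estimated correlation), and in brain, 9 with 2 higher (0.0360 and adjusted p = 0.599 with an estimated correlation). In intestine replicate 1, 15 of 18 pancreas genes were higher than in every other library. There AMY2A had 9409 CPM, CPA1 1409, PLA2G1B 1312, CTRL 1244, CTRB2 1150.2, CEL 955 and PNLIP 922. On chromosome Z, 78 of 140 tested genes between 70 and 80 Mb and 33 of 63 between 80 and 90 Mb were elevated in testis, against 10 of 102 to 25 of 104 in the bins with the lowest and highest share elsewhere.

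Samples were also regrouped at random into groups of the same sizes, with the highest count of any other split beside the real count. Over 40 splits of the tissues, elevated genes numbered 1025 in brain against 1 in the highest other split. They numbered 196 in heart, 370 in intestine, 310 in kidney, 385 in liver, 221 in lung, 401 in muscle and 2222 in testis, each against 0. The other splits mixed libraries of different tissues within groups, where hardly any gene could be 4-fold over every other group. These low counts were thus largely fixed in advance and do not decide on chance. For genes lower the real split was the highest, with 4019 against 179 in brain, 4061 against 519 in heart, 3601 against 592 in intestine, 2351 against 874 in kidney, 4131 against 1311 in liver, 3382 against 405 in lung, 7056 against 3738 in muscle and 5148 against 403 in testis. For genes higher it was 5297 against 2461 in brain, 3200 against 2060 in heart, 3784 against 3704 in kidney, 4223 against 2042 in lung, 3905 against 3518 in muscle and 7429 against 3767 in testis. Intestine had 4144 against 4219 and liver 3800 against 3809, so 2 of 40 splits gave as many. The mixed groups still held differences between tissues, so the counts of higher and lower genes do not decide on chance either. The list tests had 82 against 134, and all 40 of 40 splits gave as many, so their number does not separate the tissues from other groupings. Genes differing between animals numbered 3098 against 2 in 30 splits. Each pair was also fitted alone in 100 splits, where a split and its mirror count once and so the larger direction of each was taken. Heart had 4015 higher and 2917 lower genes than muscle against 0 and 0. Liver had 2501 and 3353 than kidney against 32 in the larger direction of any other split (1 in its other direction). Testis had 6431 and 5389 than brain against 0 and 0. Every other split put libraries of both tissues in both groups, so its low count was largely fixed in advance and does not decide on chance.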
